A study of Danaus plexippus with 48 samples.

How the data were processed

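RNA sequencing of brains of the monarch butterfly, Danaus plexippus, was deposited for 48 libraries in 3 groups. LP (long photoperiod) butterflies were kept with 15 h of light and 9 h of dark, SP (short photoperiod) butterflies with 10 h of light and 14 h of dark, and Migrant butterflies with 11 h of light and 13 h of dark, all at 21 degrees C for at least 7 days. Each group had 16 libraries, 2 at each of 8 times, which were zeitgeber time (ZT, hours after lights-on) 1, 4, 7, 10, 13, 16, 19 and 22. Each library was a pool of 3 brains, and at each time 1 pool was labelled female and the other male.

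Per the submitters' processing notes, reads were processed with CASAVA 1.8.2, aligned with TopHat2, and turned by Cufflinks into the deposited FPKM values, fragments scaled to transcript length and to mapped reads. No version of TopHat2 or Cufflinks is given in the sources used here. The deposited tables held 15130 genes with FPKM and confidence limits and paired no gene identifier with a name. The RefSeq gene table used here, of assembly MEX_DaPlex, matched 0 of the identifiers. Gene names are therefore not reported, and the 22 gene lists fixed before the data were examined were not run. Coordinates are those of the deposited tables, on a genome build that is not given in the sources used here, and a start may be off by a base or so.

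Values were analysed as log2 of FPKM plus a pseudocount of 1. Genes with a mean FPKM of 0.5 or more over the 48 libraries were tested, which left 11630 genes. Models were fitted with limma 3.58.1 in R 4.3.3, with the trend and robust options and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. Tables were joined and plots drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Mean levels were compared in a model with a mean for each of the 24 combinations of group and time, averaging the 8 time points of a group. A rhythm was tested per group as a cosine and a sine of 24 h (2 degrees of freedom), and a difference of rhythm as the difference of those terms between groups. The female minus male difference was tested in the model of 24 means. All 48 libraries entered each fit and shared the estimate of spread. The designs, the filter and the alternatives were chosen before the data were examined, except where a test is named as chosen after.

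The rule for named genes, also fixed beforehand, took those with the largest fold changes among called genes with a mean FPKM of 1 or more and the same direction at all 8 time points, or with the smallest adjusted p for rhythms. Because no gene had a name, at most 2 genes in each direction are printed by identifier per comparison. Genes outside the rule are named as chosen after their values were seen. No fold change is given where most libraries of a group were listed at 0.

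Reads per gene were recovered from the distance between FPKM and its upper confidence limit, taken as 2 times FPKM over the square root of the reads. Of the recovered values under 30 reads, 82.5% to 85.1% per library lay within 0.05 of a whole number. Because the others did not, the planned count test was not run, and recovered reads were used only for depth and for a voom alternative. Reads in genes ranged from 5.47 M to 10.6 M per library (M, 1e6 reads). A gene with fewer than 10 reads per library is named as resting on few reads.

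Alternatives were a pseudocount of 0.1, no filter or a mean FPKM of 2 or more, median-ratio scaling, quantile normalization, sex or replicate number as a covariate, each library left out in turn, other settings of the empirical Bayes step, a model with 24 h and 12 h cosines, an F-test over time points (7 degrees of freedom), fits to the compared groups alone and a Wilcoxon test. Alternatives added after the data were examined were voom, a minimum of 10 reads, library quality weights, leaving out outlying Migrant libraries, removal of the trend with gene length or of the main axis of spread between SP replicates, exchanged SP sex labels, and LP with Migrant libraries only. For each count, 100 splits were drawn, the real one included, exchanging groups or sex labels within time points, or times within a group.

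The models were tested on simulated data with the real mean of each of 11630 genes and 1 spread per gene for all groups. In each comparison 200 genes were changed. The simulated groups thus did not differ in spread, and recovery differs between groups and comparisons only by the genes and noise drawn. In the data the median residual SD was 0.148 in LP, 0.298 in SP and 0.267 in Migrant, each fitted alone. At a log2 fold change of 0.5, 81% of changed genes were recovered for SP versus LP, 68% for Migrant versus LP and 62% for Migrant versus SP. At a log2 amplitude of 0.5, 60% were recovered in LP, 69% in SP and 66% in Migrant. Of genes with an amplitude of 1 in 1 group alone, the test of a difference recovered 85% for SP versus LP, 85% for Migrant versus LP and 73% for Migrant versus SP.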

Results

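Gene expression in monarch butterfly brains was measured around the day by RNA sequencing, with 16 libraries in each of the groups LP, SP and Migrant. Each library was a pool of 3 brains, with 2 pools at each of 8 times. Reads in genes averaged 9.0 M ± 1.02 (SD, n = 16) in LP, 7.27 M ± 0.97 in SP and 6.94 M ± 0.61 in Migrant (M, 1e6 reads), and ranged from 5.47 M to 10.6 M. All Migrant libraries, and none from LP or SP, were made with another kit from wild-caught butterflies, so kit, origin and group cannot be told apart. The first principal component held 57.1% of the variance and set SP apart, and the second held 11.2%.

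**Figure D1:**
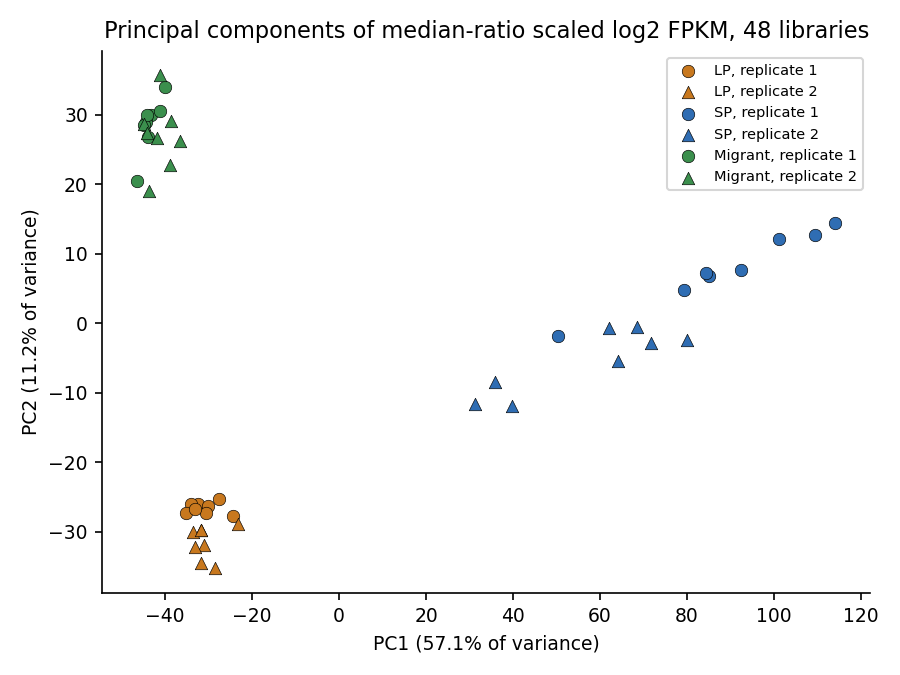
Principal components of the 48 libraries after median-ratio scaling, with 1 point per library, colour for group and shape for replicate number. PC1 (57.1% of variance) spreads the SP libraries widely, and PC2 (11.2%) parts LP from Migrant.

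The comparison of SP with LP asked which genes differ in mean level between short and long days. Most tested genes differed. Of 11630 genes, 9310 were called (limma), 4563 higher and 4747 lower in SP. Larger falls were more frequent than larger rises: 716 genes were at least 2-fold higher and 2325 at least 2-fold lower. Fold changes from LP were lower in longer genes (Spearman rho -0.191), and whether this gave the excess of larger falls was not tested. At all 8 time points the direction was the same for 8377 of the called genes. The spread between pairs of libraries of a group, over counting noise (chi-squared per degree of freedom), reached 105 in SP, 17.7 in LP and 113 in Migrant, where Migrant ZT22 replicate 1 stood apart, with a correlation of 0.874 with the other library of its time. The differences between the 2 SP libraries of a time point ran along the same genes as the difference from LP.

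DPOGS203061 (scaffold DPSCF300392, 17 to 886) had a mean FPKM of 12.5 ± 3.15 in LP and 199 ± 198 in SP (SD, n = 16 each), a log2 fold change of 3.26 ± 0.32 (SE, limma adjusted p = 3.99e-10). DPOGS213995 (DPSCF302071, 310 to 434) rose from 16.4 ± 25.2 to 104 ± 60.7, a log2 fold change of 3.68 ± 0.64 (limma adjusted p = 8.52e-06), on few reads. It was listed at 0 in 6 of 16 LP libraries, so its fold depends on the pseudocount. DPOGS203705 (DPSCF300010, 1559138 to 1559270) and DPOGS213296 (DPSCF300479, 17069 to 17148) had the lowest fitted values. They were listed at 0 in 12 and 11 of 16 SP libraries and in 0 of 16 LP libraries, where their mean FPKM was 4736 ± 1799 and 637 ± 247. Both rested on under 10 reads per library, and no fold is given.

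Migrant was compared with LP and SP to place migratory butterflies beside the laboratory groups. Most genes had lower FPKM in Migrant, a shift that scaling removed. Of 11630 genes, 8260 differed from LP as deposited, 889 higher and 7371 lower, so that 10.8% of calls were higher. With median-ratio scaling, 5847 differed, 2750 higher and 3097 lower, or 47% higher. The median log2 fold change was -0.385 as deposited and -0.026 after scaling. Against SP, 9506 genes differed as deposited, 3436 higher and 6070 lower, and 9520 after scaling, 4811 higher and 4709 lower.

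DPOGS207200 (DPSCF300001, 5812782 to 5813623) had a mean FPKM of 1.34 ± 0.41 in LP, 1.89 ± 0.93 in SP and 48.9 ± 9.82 in Migrant (SD, n = 16 each). Its log2 fold change from LP was 4.41 ± 0.10 (SE, limma adjusted p = 1.16e-22). The pseudocount of 1, near the LP mean, makes this fold smaller than the ratio of the mean FPKM. DPOGS213995 was higher still on few reads, at 307 ± 201 in Migrant (5.24 ± 0.64, limma adjusted p = 6.04e-08). DPOGS211342 (DPSCF300173, 726957 to 728023) fell from 1752 ± 1137 in LP and 2645 ± 2217 in SP to 10.8 ± 8.95 in Migrant, with log2 fold changes of -7.47 ± 0.50 from LP (limma adjusted p = 8.21e-13) and -7.88 ± 0.50 from SP, on 2.8 reads per Migrant library. DPOGS213566 (DPSCF300033, 5129 to 5247) was listed at 0 in all 16 Migrant libraries and at 57.1 to 278 FPKM in LP and 144 to 720 in SP, on few reads.

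Genes with lower expression in Migrant clustered in 1 region. On scaffold DPSCF300307, 9 of 25 tested genes were at least 2-fold lower in Migrant than in LP after scaling, where 0.6 were expected (one-sided Fisher's exact test over 294 scaffolds, adjusted p = 1.44e-06). They lay between 79099 and 161575. For 8 of them log2 fold changes ran from -3.30 to -2.07, and the other was listed at 0 in 15 of 16 Migrant libraries. In Migrant 6 of the 9 had under 10 reads per library. Of the 9, 8 were higher in SP than in LP. The test takes genes as independent, but 4 of the 9 had the same length and several had near-equal values, so reads shared between copies make this count uncertain. No scaffold (0 of 294) held more genes at least 2-fold higher in Migrant than expected by that test.

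**Figure D2:**
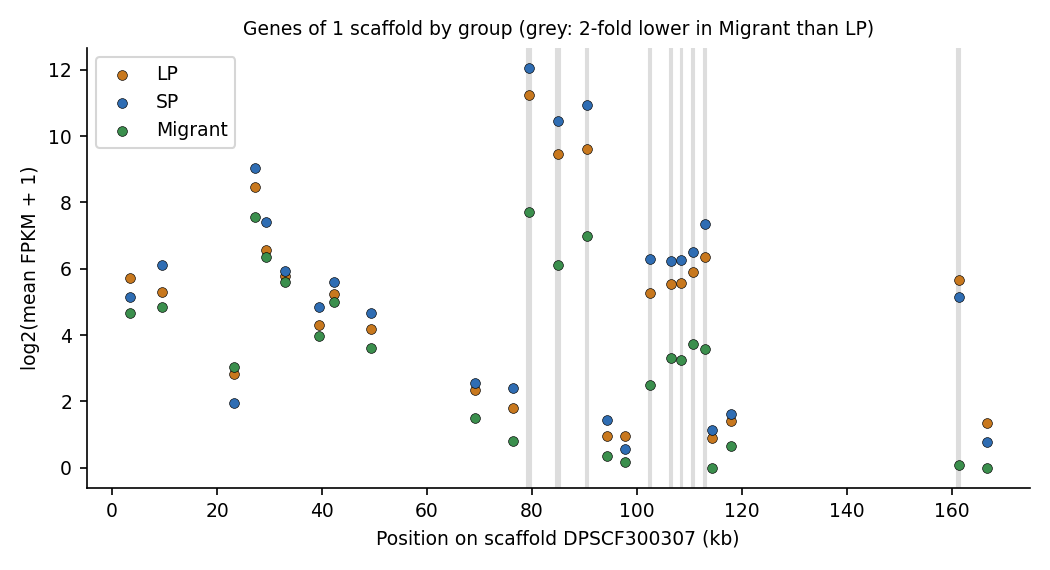
Mean FPKM on a log2 scale with a pseudocount of 1, by position in kb on scaffold DPSCF300307, with 1 point per gene and group (n = 16 libraries each). Grey bands mark the 9 genes at least 2-fold lower in Migrant than in LP, which lay between 79099 and 161575.

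SP and Migrant, which both had shorter days than LP, were compared for genes that differed from LP in the same direction. As deposited, 3496 genes did so, 381 higher and 3115 lower, where independent lists would share 348.8 and 3008.6. Both comparisons use the same LP libraries, so chance sharing lies above these independent counts. Fold changes from LP correlated at 0.095 across genes, which are not independent replicates, with a covariance of 0.052. Unchanged groups simulated against the same LP libraries gave 0 genes (limma), a correlation of 0.498 and a covariance of 0.0123. With no real differences to call, that 0 is no baseline for the count. Median-ratio scaling, which centres the fold changes, gave 1257 higher and 1442 lower, where independent lists would share 1118 and 1249.5. With the LP libraries split between the comparisons, the lists as deposited shared no more than independent ones in total: 250 higher and 2100 lower against 251 and 2206.2 in 1 split, and 244 and 2163 against 224.5 and 2281.9 in the other. After scaling, the splits shared 787 and 843 against 722.9 and 804.7, and 707 and 731 against 636.5 and 691.2. The splits went by replicate number, which in LP runs with the sex label. SP was thus compared with LP pools of 1 label and Migrant with those of the other. LP pools differed by label for 1957 genes (limma), and what this did to the sharing was not tested. DPOGS215455 (DPSCF300098, 619109 to 619425), chosen after its values were seen, had log2 fold changes of -2.60 ± 0.15 in SP and -3.06 ± 0.15 in Migrant, on 2.5 reads per SP library and 2.1 per Migrant library.

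Genes with a 24 h rhythm were sought in each group, since the study asked which rhythmic genes accompany responses to day length. A rhythm was called for 52 genes in LP, 108 in SP and 177 in Migrant (limma), and 37 genes were called in every group. Single libraries moved these counts: without Migrant ZT22 replicate 1 they were 82 in LP and 281 in SP, without SP ZT1 replicate 1 the SP count was 190, and without Migrant ZT10 replicate 2 the Migrant count was 114. Of the LP genes, 49 were also called in SP and 38 in Migrant, where independent lists would share 0.48 and 0.79. The tests use the same spread per gene, so chance sharing may lie above these. At least 1 other group shared 50 of 52 LP calls, 65 of 108 SP calls and 54 of 177 Migrant calls. Peaks fell in the light for 86.5% of LP genes, 34.3% of SP genes and 70.1% of Migrant genes, while light filled 62.5%, 41.7% and 45.8% of the day. In fits to each group's own libraries the shares were 82.1%, 41.7% and 65.3%. In Migrant, 68 of the 177 peaks fell at ZT 9 to 12, but 6 of 49 in the fit to its own libraries. The share without Migrant ZT10 replicate 2 was not computed. The unadjusted test passed 310 genes in LP, 1016 in SP and 1818 in Migrant, where 582 were expected by chance. Fits to each group's own libraries called 140, 48 and 49 genes, and their unadjusted test passed 914, 797 and 955. The shared spread had a median residual SD of 0.279, against 0.148, 0.298 and 0.267 in LP, SP and Migrant alone. Sharing it makes the test stricter in LP, so these counts do not rank the groups. In SP, 21 of 100 exchanges of the times between libraries gave as many genes.

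DPOGS204644 (DPSCF300462, 48480 to 60775) had log2 amplitudes of 1.26, 1.40 and 1.24 (SE 0.10 each) and peaked at ZT 1.20 in LP, 23.3 in SP and 22.8 in Migrant (limma adjusted p = 2.77e-11, 6.42e-13 and 4.49e-11). DPOGS208606 (DPSCF300052, 257703 to 259229) peaked at ZT 11.3, 9.70 and 8.59 with amplitudes of 1.34, 1.28 and 1.02 (SE 0.12 each). DPOGS209925 (DPSCF300180, 115531 to 130653) peaked near dusk in LP, at ZT 15.3, and at ZT 13.8 and 13.5 in SP and Migrant.

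**Figure D3:**
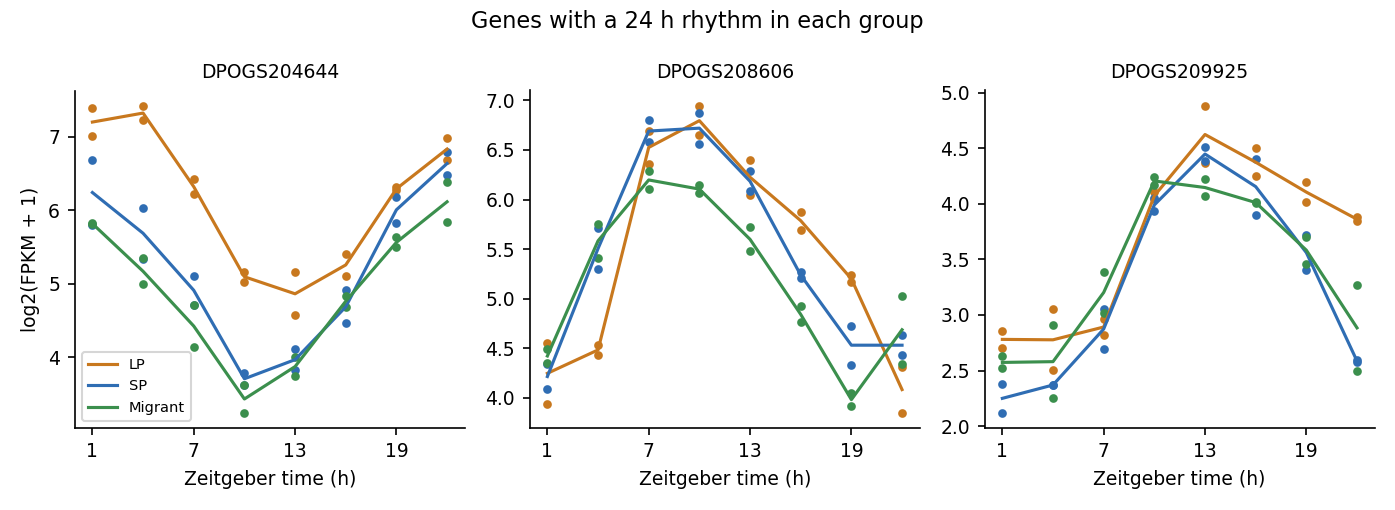
Expression, as log2 of FPKM plus 1, against zeitgeber time in hours for 3 genes, with a point per library and lines through the mean of the 2 libraries at each time. DPOGS204644 peaked at ZT 1.20 in LP, 23.3 in SP and 22.8 in Migrant.

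Peaks came earlier in SP and in Migrant than in LP, and earlier in Migrant than in SP, although Migrant had the longer day of the latter pair. Among 49 genes rhythmic in LP and SP, 47 peaked earlier in SP, by a median of -1.59 h (interquartile range -2.32 to -1.02). All 38 genes rhythmic in LP and Migrant peaked earlier in Migrant, by a median of -2.55 h (-3.15 to -1.6). Of 53 genes rhythmic in SP and Migrant, 42 peaked earlier in Migrant, with a median of -1.27 h (-1.9 to -0.31). This test of the genes together was chosen after the peaks were seen, and was not repeated without the outlying Migrant libraries.

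**Figure D4:**
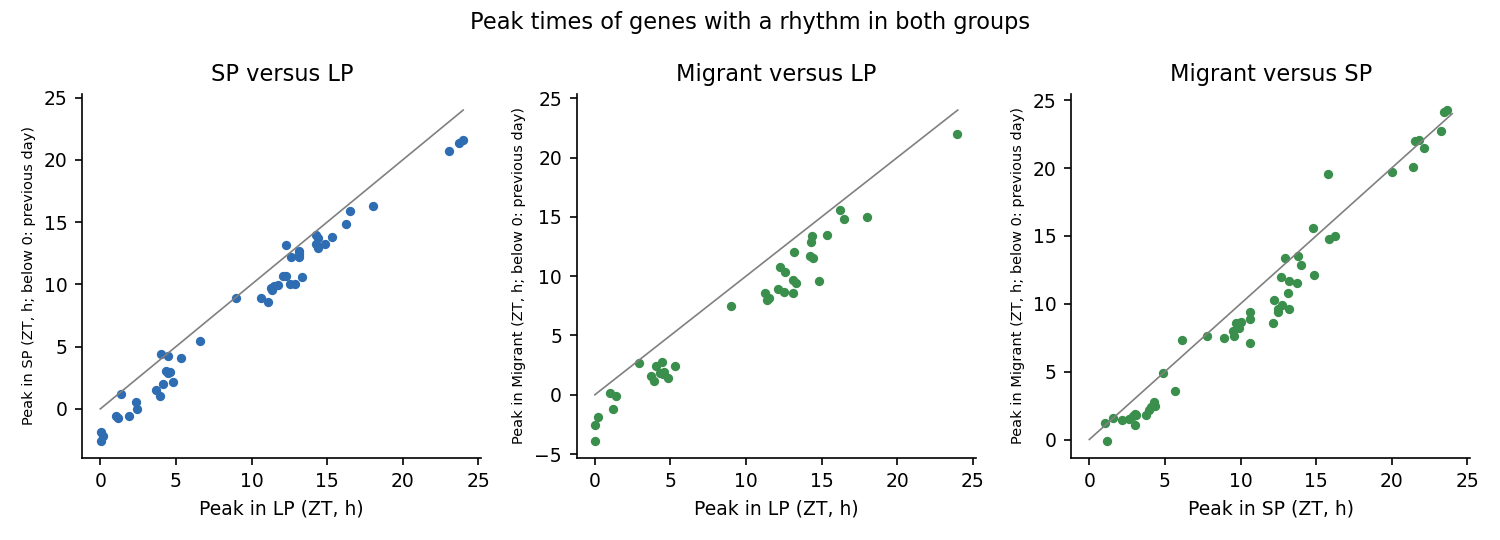
Peak times in hours for genes rhythmic in both groups of each comparison, with 1 point per gene and a grey line where both peaks are equal. Points below the line, 47 of 49 for SP versus LP and 38 of 38 for Migrant versus LP, peaked earlier in the group on the vertical axis.

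Rhythms were also compared gene by gene. Adjusted over all tested genes, none was called between SP and LP (0 with limma, 261 at an unadjusted p under 0.05, lowest adjusted p = 0.223), and 1 was called by voom. Between Migrant and LP, 2 were called: DPOGS209146 (DPSCF300061, 615676 to 618767), which peaked at ZT 14.8 in LP and 9.64 in Migrant (limma adjusted p = 0.0255), and DPOGS204644 (adjusted p = 0.0341). The first call was lost under 8 of 65 alternatives and the call of DPOGS204644 under 18 of 65. Between Migrant and SP, DPOGS206025 (DPSCF300028, 1708649 to 1733729) was called, with an amplitude of 0.75 ± 0.09 in SP and 0.21 ± 0.09 in Migrant (limma adjusted p = 0.000102). Adjusted over rhythmic genes only, the counts were 26, 115 and 83, but those genes were selected by a rhythm test on the same libraries.

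Pools labelled female and male were compared within time points. Over all groups 12 genes differed, 3 higher in pools labelled female and 9 higher in pools labelled male (limma). This count ranged from 3 to 1059 with 1 library left out (1059 without Migrant ZT22 replicate 2), and moved by over 1.5 times for 42 of 48 libraries. Because each group and time has its own mean, leaving out 1 library takes its whole pair from this test. The 1059 thus also lacks the outlying Migrant ZT22 replicate 1. DPOGS203381 (DPSCF300003, 479017 to 484928) had a female minus male log2 difference of 0.48 ± 0.08 (SE, limma adjusted p = 0.0205), in the same direction in 21 of 24 pairs. DPOGS209090 (DPSCF300485, 46740 to 47269) differed by -0.46 ± 0.09 (adjusted p = 0.0366), in 22 of 24. The call of DPOGS203381 was lost under 4 of 63 alternatives and that of DPOGS209090 under 42 of 63. Both calls were lost with the SP sex labels exchanged, at 0.25 and -0.30 (limma adjusted p = 0.147 and 0.091). Both were also lost with the main axis of spread between SP replicates removed (limma adjusted p = 0.395 and 0.492). Groups taken alone gave 1957 genes in LP, 790 in SP and 14 in Migrant. Spread differed between the groups, and Migrant held the outlying ZT22 replicate 1, so these counts do not rank the groups. Across all genes, which are not independent replicates, the differences of SP correlated at -0.128 with LP and -0.103 with Migrant, and those of LP and Migrant at 0.1. Of 12 genes called with 1 sign in LP alone and in Migrant alone, 11 were called with the opposite sign in SP. DPOGS212555, chosen after its values were seen, was listed at 0 in 8 of 8 LP pools labelled female, 8 of 8 Migrant pools labelled female and 7 of 8 SP pools labelled male. With this reversal between groups, no direction by sex is given beyond the labels.

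**Figure D5:**
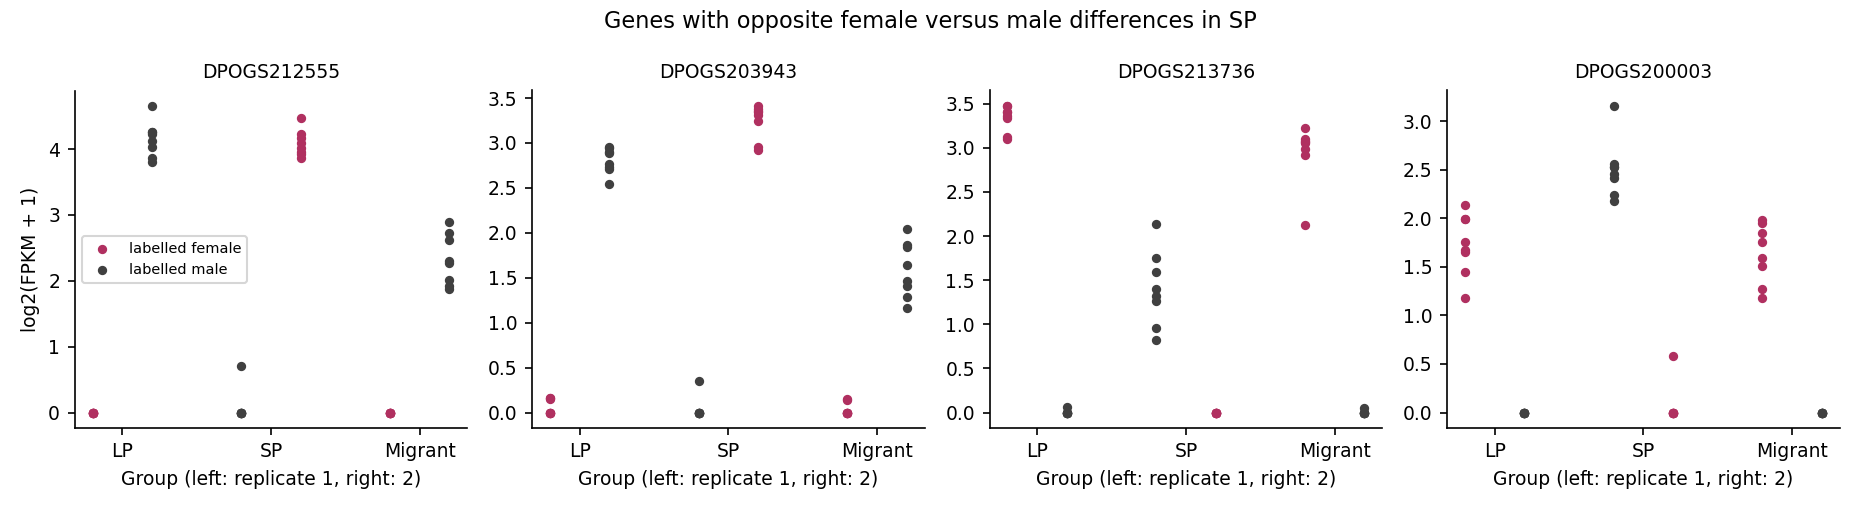
Expression, as log2 of FPKM plus 1, of 4 genes chosen after their values were seen, with 1 point per library by group, replicate number and sex label. DPOGS212555 was listed at 0 in 8 of 8 LP pools labelled female and in 7 of 8 SP pools labelled male.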

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

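The tests of differences of the female minus male difference between groups, and every test of an explanation in this part, were chosen after the results were seen.

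Differences between groups set the following results apart. The rhythm differed for 2 genes between Migrant and LP and for 1 gene between Migrant and SP. Chance was not excluded for these counts: 9 and 14 of 100 splits of the libraries gave as many genes, the highest other splits 4886 and 7797. These splits exchange groups at part of the day and so carry differences of mean level into the rhythm, and why they gave so many genes was not tested. The female minus male difference itself differed for 2972 genes between SP and LP, for 9 between Migrant and LP and for 3566 between Migrant and SP. In SP the sex label ran with the main axis of spread between replicates, on which the pool labelled male lay higher at 7 of 8 times, so these counts with SP do not part sex from that axis.

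Of the 12 genes called with 1 sign in LP alone and in Migrant alone, 11 were called in SP with the opposite sign, at 8 of 8 times, ZT19 included, where the SP axis ran the other way, DPOGS200090 was not called, and across all genes SP correlated at -0.128 with LP and -0.103 with Migrant, beside 0.1 for Migrant with LP. A reversal by days of 11 h or less is argued against by Migrant, where the genes of the scaffolds lower in LP pools labelled female differed by -0.068 ± 0.026 (SD over 8 time points), with the sign of LP. A candidate explanation is an exchange of the sex labels of the SP pools at every time, or of the labels of LP and Migrant. Which labels are right was not decided. Of 294 scaffolds, 10 held more genes higher in LP pools labelled male than expected (one-sided Fisher's exact test). For genes higher in LP pools labelled female, 0 did. What this says about the labels was not tested. A difference between short and long days in sex effects that Migrant butterflies do not share stays open and untested.

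The differences of SP from LP followed the differences between the 2 SP libraries of a time point, with a median correlation across genes of 0.623 (from -0.62 at ZT19 to 0.865) against -0.023 for LP and -0.061 for Migrant libraries. Gene length as the whole cause of the calls is argued against, since 8371 of the 9310 kept their direction with the length trend removed. The correlation was not computed again after that step. With the main axis of the SP replicate differences removed, 6058 calls kept their direction, so the count of kept calls does not test the correlation. Whether length gave the correlation, or a part of the calls, stays open. The median SP minus LP log2 fold change was -0.593 in the longest 10% of genes and -0.039 in the shortest 10%. Its Spearman rho with gene length was -0.191. A sex difference alike in LP and SP is argued against, since the replicate differences of LP and SP correlated across genes at 0.128, but 1 particular to SP stays open, as the pool labelled male lay higher at 7 of 8 times. A graded quality of RNA or libraries in SP may give this pattern, and so may a response to short days that varied between pools. The 0.623 cannot tell them apart. The 10 genes with most reads in a library held 9.8% ± 1.2 of reads in SP and 7.3% ± 0.2 in LP (SD, n = 16 each). Migrant ZT22 replicate 1, which stood apart, held 9.2%. It lay at 53.3 on the SP axis, against 16.2 to 24.1 for the other Migrant libraries and 36.4 to 146.9 in SP. As 1 library, it does not decide between these readings.

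Most genes had lower FPKM in Migrant than in LP. The median log2 fold change was -0.385 as deposited and -0.026 after median-ratio scaling. Gene reads per FPKM normalizer were lower by a similar amount, -0.445 as a log2 ratio, but are computed from the same values and so do not test the cause of the shift. Calls left after scaling, 3986 of them with the direction they had before, stay open to library kit and origin, which cannot be told apart from group. A biological difference of migratory butterflies stays open and untested.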

How the results depend on the processing

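Alternatives named as added were chosen after the data were examined. The 3 counts of genes differing in mean level stayed within 1.5 times of the reported counts under each alternative run, but the genes called changed more. For Migrant versus LP, 3986 of 8260 calls kept their direction with median-ratio scaling and 3621 with voom (added). For SP versus LP, 9235 of 9310 did with scaling, 8770 with voom (added) and 6058 with the SP axis removed (added). Leaving out each library in turn gave 9133 to 9556 genes for SP versus LP, 8060 to 8576 for Migrant versus LP, 9398 to 9622 for Migrant versus SP and 3324 to 3698 for the same direction in both. That last count was 258 with a log2 fold change of 1 or more, by construction, and 1841 with the axis of spread between SP replicates removed (added).

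Counts of rhythmic genes moved more. The shared spread lay above that of LP alone, which makes the test stricter there, and other causes were not tested. Fits to the group's own libraries gave 140 genes in LP, 48 in SP and 49 in Migrant, and the F-test over time points 25, 41 and 48. The model with 24 h and 12 h cosines gave 63 in SP and 96 in Migrant, and quantile normalization 382 in Migrant. Added alternatives gave, for LP, SP and Migrant, 94, 315 and 116 without the outlying Migrant libraries, 209, 42 and 325 with quality weights and 99, 304 and 628 with the SP axis removed. Leaving out libraries gave 47 to 82 in LP (82 without Migrant ZT22 replicate 1), 85 to 281 in SP (281 without that library and 190 without SP ZT1 replicate 1) and 114 to 218 in Migrant (114 without Migrant ZT10 replicate 2).

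The count of different rhythms between SP and LP, 0 with limma and 261 at an unadjusted p under 0.05, was 1 in the groups' own libraries, 1 with voom (added), 1 with quality weights (added) and 26 when adjusted over rhythmic genes only, with fewer genes tested. Leaving out libraries gave 0 to 2 (2 without Migrant ZT22 replicate 1, 1 without SP ZT4 replicate 1). Between Migrant and LP it was 5 with median-ratio scaling, 8 with quantile normalization, 1 with the time point F-test, 115 over rhythmic genes only and, added, 31 with quality weights, 1 with the length trend removed and 15 with the SP axis removed. It ranged from 0 to 7 with a library left out. It was 7 without LP ZT1 replicate 1, 5 without Migrant ZT22 replicate 1, 4 without Migrant ZT19 replicate 1, 0 without LP ZT4 replicate 2, either LP ZT7 library, LP ZT22 replicate 2 or Migrant ZT16 replicate 1, and 1 without LP ZT4, ZT16 or ZT22 replicate 1, Migrant ZT4 replicate 1, ZT1, ZT10, ZT13 or ZT19 replicate 2, or either Migrant ZT7 library. Between Migrant and SP it was 83 over rhythmic genes only and, added, 4 without the outlying libraries, 2 with quality weights and 6 with the SP axis removed, and ranged from 1 to 2 (2 without Migrant ZT22 replicate 1). The cause was not tested.

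The count of 12 genes by sex label was 6 without the filter, 45 with quantile normalization, 1957 in LP alone and 790 in SP alone. Added alternatives gave 895 without the outlying libraries, 977 with quality weights, 6 with the length trend removed, 0 with the SP axis removed (limma), 982 with SP labels exchanged and 337 in LP with Migrant. Leaving out libraries gave 3 to 1059. It moved over 1.5 times for 42 of 48 libraries, all except both libraries at LP ZT4, LP ZT19 and SP ZT13. It was 1058 and 1059 without Migrant ZT22 replicate 1 and 2, 208 and 205 without SP ZT19 replicate 1 and 2, and 20 without either SP ZT10 library. Both libraries of a pair gave near-equal counts because leaving out 1 takes the pair from this test. The Migrant ZT22 pair holds the outlying replicate 1. Why other pairs moved the count was not tested.

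Replicate numbers did not pair the samples: 24 correlations of deviations between groups ranged from -0.122 to 0.163, with 3 over 0.1. With a replicate block the level counts were 9395, 8408 and 9634, the shared direction 3614, the rhythms 64, 130 and 196, and the differences of rhythm 0, 3 and 2. For sex labels the block gave 3202 genes, since replicate number and sex label differ only in SP. Of 3178 alternatives for 50 results on named genes, 3080 kept their call, 98 lost it and 0 reversed. Alternatives for the gene lists, and the count test, were not run. Genes with fewer than 10 reads per library are limited by depth.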

Other observations

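All tests in this part, splits of the libraries included, had their reading written after the results were seen.

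Splits of the libraries showed where chance can be excluded. For mean levels 1 of 100 splits, the real one, gave as many genes, with 9310, 8260 and 9506 genes beside highest other splits of 7514, 5342 and 7729. The same held for rhythms in LP (52 against 3) and Migrant (177 against 11) and the sex labels (12 against 0, limma, with 2096 at an unadjusted p under 0.05), although exchanged SP labels gave 982. For the shared direction, 1 of 100 splits, the real one, gave as many (3496 against 1). Such splits remove the group differences and do not test sharing by chance. Counts of independent lists do not settle it either, since both comparisons use the same LP libraries. With the LP libraries split, the total was not above that of independent lists as deposited, but was above it after scaling. Those splits also parted the LP pools by sex label, so they do not settle it. For the count of rhythms in SP chance was not excluded, as 21 of 100 splits gave 108 genes or more and the highest 4328, which points to a structure among the SP libraries that was not tested. Of the 108 genes, however, 49 were also called in LP, where independent lists would share 0.48. Both tests use the same spread per gene, so chance sharing may lie above 0.48. Peaks lay within 3 h for all 49, which a shared spread does not bring about, so chance does not account for these. For different rhythms between SP and LP, 100 of 100 splits gave as many as the real 0 (limma, 261 at an unadjusted p under 0.05; highest 7141), the only possible outcome, so this says nothing about chance.

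Migrant ZT22 replicate 1 had 678 genes over 4-fold below its group median, where the highest of the other 47 libraries had 103. Migrant ZT10 replicate 2 had 88 genes over 4-fold above, against 24.

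Peaks were tested against the times of light. A fixed time from lights-on would leave the median difference between SP and LP near 0, but it was -1.59 h, and the largest of the other splits of 100 gave 1.36 h. A fixed time from the middle of the light would put Migrant 0.5 h later than SP, but the median was -1.27 h, and 2 of 100 splits were as large (largest other 1.4 h). It would put SP at -2.5 h from LP, outside the interquartile range of -2.32 to -1.02 but within the full range, which reached -2.88. It would put Migrant at -2 h from LP, which lay within the interquartile range of -3.15 to -1.6. These ranges are spreads over genes and do not test the predicted values. The splits exchange groups at part of the day and so carry differences of mean level into the peaks. They are thus no clean baseline for the medians. Among these genes, 47 of 49 peaked earlier in SP than in LP, which argues against the first reading as a whole explanation. Only Migrant versus SP, where 42 of 53 peaked earlier in Migrant, goes against the second. It was not repeated without the outlying Migrant libraries, and kit and origin also part these groups, so the second is not decided.

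A rhythm averaged over the 3 groups, tested after the data were examined, was called for 246 genes, 101 of them in no group alone. Such a call does not show a rhythm shared by all groups. DPOGS206025 was called (limma adjusted p = 0.0101). Its amplitudes were 0.11 ± 0.09 in LP, 0.75 ± 0.09 in SP and 0.21 ± 0.09 in Migrant (SE). Its fitted peaks lay at ZT 23.4 in SP and 9.34 in Migrant. On scaffold DPSCF300218, 8 of 25 tested genes were called in this averaged test, where 0.5 were expected (one-sided Fisher's exact test, adjusted p = 8.33e-06). Near-equal values of several of them leave open reads shared between copies.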
